A study of Caulobacter vibrioides NA1000 with 16 samples.

How the data were processed

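RNA was measured by RNA-seq in 16 samples of Caulobacter vibrioides NA1000, an aquatic alphaproteobacterium. The samples came from 4 strains called JS38, JS221, JS233 and JS299, each taken before rifampicin (0 min) and at 1, 3 and 9 min after 200 µg/mL of the drug. There was 1 library per strain and time point, so no value has a replicate. Per the labels' protocols, overnight cells in medium with 0.2% xylose were washed and grown for 8 h with 500 µM vanillate before treatment. That protocol names JS299 and is repeated word for word for every sample, so whether the other strains had the same media is not given in the sources used here. Per the same protocols, libraries were made from 5 µg of total RNA after removal of ribosomal RNA by a kit. The labels do not tell which strain carries which change, so JS38 served as the reference only because it comes first, and all 6 pairs of strains were computed.

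Reads were aligned with Bowtie 0.12.8, per the submitters' processing notes. The genome build, the annotation, the counting tool and the use of strand are not given in the sources used here. The table the authors deposited holds RPKM (reads per kilobase of feature length, relative to the depth of the library), with 1 column per sample and 2450 features. Of these, 2255 are numbered operons, 138 are non-coding RNAs with CCNA_R tags, 51 are tRNAs and 6 are rRNAs, the last all blank. The unit was read from the values, since no label names it. For the non-coding RNAs, whose lengths are known from the reference, each RPKM value times the length less 1 fell on a whole multiple of 1 constant per library (100% of values within 0.02 reads). That constant gave the depth of every library, between 4841645 and 16277037 reads, and the lengths of 2065 operons. Operon lengths were accepted only if no value fell below 51 reads, so the lowest recovered value of 51 or 52 reads per library is partly built in. The non-coding RNAs of known length are free of that rule, and among them CCNA_R0151 had 52 reads in JS38 at 0 min. A blank was taken to mean 50 reads or fewer, which is an assumption. The 156 features that are blank in all 16 libraries were not interpreted. Recovered lengths and reads were used for depth, limits and counting intervals, and no count test was run. On simulated tables the same procedure recovered the depth of all 16 libraries and the exact length of 98.3% of 530 operons. Those tables were themselves blanked at 50 reads or fewer, so they do not check that limit.

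All 138 non-coding tags matched locus tags of the reference gene table (assembly ASM2200v1), which gave the names chvR, crfA and gsrN. Neither the deposited table nor that gene table pairs the operon numbers with genes, so operons carry no gene names here, and at most 2 operons are named per direction. The build behind the deposited table is not named, so no coordinates are printed. Some annotated non-coding RNAs overlap each other, among them crfA and CCNA_R0079, and reads in such overlaps are uncertain.

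A half-life was the natural logarithm of 2 divided by the fitted rate from a least-squares line of ln(RPKM) on time over the 4 time points. It was computed only where all 4 values of the strain were present and the slope was negative. RPKM is relative to all reads of a library, and stable RNAs such as tRNA take a growing share of the reads after rifampicin, so fitted half-lives are longer than absolute ones. The error given with a single half-life is the standard error of the fit over 4 points. The interval given with a median is the 95% order-statistic interval over features, and features are not replicates. In data simulated from the 0 min levels and half-lives of JS38, with 200 operons doubled in half-life in JS299, the median log2 ratio over the 182 doubled operons with a ratio was 1.01 and that over 240 unchanged ones was -0.0053.

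Decay slopes were compared with limma 3.58.1 (empirical Bayes moderation with a trend on mean level wherever no value was missing) on log2(RPKM + 1), with an intercept and a slope per strain in 1 fit of all 16 samples (8 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 556 features with all 16 values and a threshold of 0.05. Time in minutes entered as a straight line. The spread in that test is the scatter about the lines within 1 culture per strain, so its p-values do not measure variation between cultures, and curvature counts as scatter. In simulated data of 556 features with 200 slopes halved in JS299, 70% of the halved slopes were called slower against JS38. There were 10 other calls in that comparison and 0 in the unchanged JS221 comparison. The simulated courses were straight lines with noise drawn independently for each feature and library. Errors shared by all features of a library or culture were not simulated, so false calls from them are not covered. Levels at 0 min were compared as ratios with no test, for operons on log2(RPKM + 1), which understates changes of low features, and for non-coding RNAs as plain ratios with 95% counting intervals, from the normal approximation to the log ratio of 2 Poisson counts. Intervals of rank correlations came from 2000 bootstrap draws of features. Reads carry no molecular identifiers, so those intervals cover counting error only.

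The design, the alternatives and the rule for named genes were fixed before the data were examined. For each pair with JS38, the rule took the 6 largest and the 6 smallest half-life ratios among features with half-lives of 0.2 to 27 min in both strains and a mean 0 min level above the median, leaving out tRNA and rRNA, plus the extreme members of each list described, plus fixed genes of the RNA degradosome, the inducible loci and the cell cycle. The fixed genes could not be located among numbered operons. Non-coding RNAs described by their 0 min level or by a limma call lie outside that rule and were chosen after their values were seen. The 3 comparisons with JS38 share its libraries, so they are not independent of each other. Of 20 gene lists fixed at the same time, only the non-coding RNAs and the tRNAs could be matched to features, and the other 18 were not used here. The half-life ratio of the non-coding list was ranked among 10000 random lists, each drawing 1 of the 20 features nearest in mean 0 min level per member. A percentile needed at least 4 members, and the tRNA list had 1 with a half-life in both strains of each pair. Alternatives covered the range and fit quality of half-lives, the feature set, time points left out, the level filter, the centring, the size rule, the pseudocount and the samples in the fit. Chosen after seeing the data were scaling to the summed RPKM of the 36 tRNAs with a value in every library, a time curve shared by the strains, a fit with at least 3 values per strain, and operons chosen by 0 min level. The last are 556 operons for which 50 reads corresponded to at most 10% of the 0 min level in every later library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.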

Results

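The series profiled RNA decay in 4 strains of Caulobacter vibrioides NA1000 described by the submitters as mutants of BR-bodies. BR-bodies are condensates of RNA and protein that form around RNase E, the endonuclease at the core of the bacterial RNA degradosome. Rifampicin blocks the start of transcription, so the level of each transcript after its addition follows the decay of RNA already made. Each of JS38, JS221, JS233 and JS299 was sampled at 0, 1, 3 and 9 min, with 1 library per strain and time point and no replicates. Depth was 4841645 to 11604837 reads per library in JS38, 12771316 to 15958073 in JS221, 10902545 to 16277037 in JS233 and 9895165 to 15981529 in JS299. The shallowest library was JS38 at 1 min. Values were present for 2171 features in JS38 at 0 min and for 580 at 9 min, against 2261 and 1494 in JS299. The blanks were taken as 50 reads or fewer.

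Operon transcripts lost most of their share of the reads within 9 min in every strain. In JS38 operons took 28.2% of the library reads at 0 min and 4.81% at 9 min. The share went from 31.6% to 8.32% in JS221, from 24.2% to 5.92% in JS233 and from 44.7% to 19.3% in JS299. Blanks and operons with no recovered length are left out of these shares, which are therefore lower bounds. Blanks were most frequent in JS38 at 9 min (1870 features). The summed level of 36 tRNAs at 9 min was 1.41 times that at 0 min in JS38, 1.44 times in JS221, 1.30 times in JS233 and 1.61 times in JS299. Non-coding RNAs with CCNA_R tags stayed between 1.90% and 3.63% of the reads across the 16 libraries.

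The question behind the time course was how fast mRNA disappears in each strain. Over the 462 operons with a value in every library, the median level at 9 min was 9.41% of the 0 min level in JS38 (95% interval over operons 7.80 to 11.3), 18.3% in JS221 (16.3 to 20.7), 21.3% in JS233 (20.3 to 22.9) and 31.1% in JS299 (28.7 to 34.0). At 3 min the medians were 51.1%, 57.1%, 62.5% and 74.8% in the same order. At 1 min they lay between 84.3% in JS221 and 97.6% in JS299. Requiring a value in every library favours stable operons. Among 556 operons chosen by their 0 min level, with blanks set at their upper limit, the medians at 9 min were 4.26%, 8.37%, 13.4% and 20.4%.

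**Figure D1:**
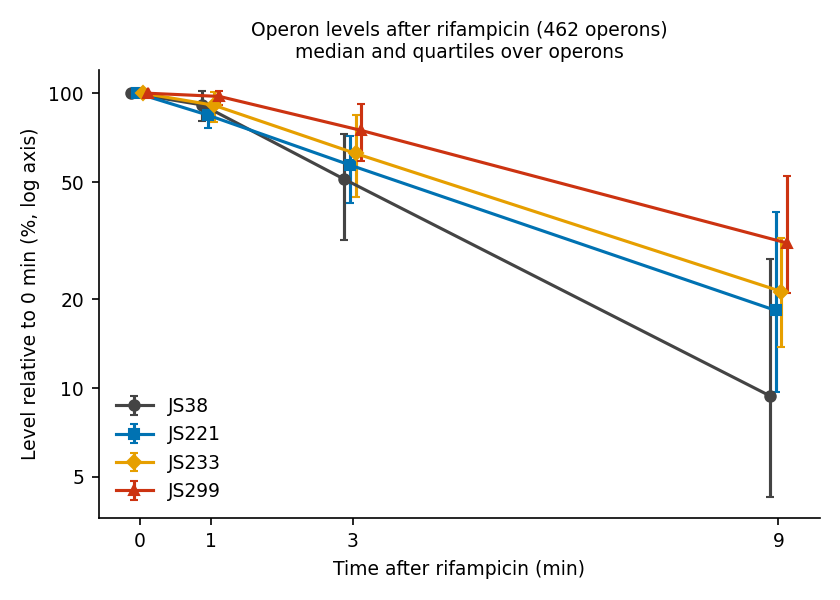
Level relative to 0 min (%, log axis) against time after rifampicin (min) for the 462 operons with a value in all 16 libraries; points are medians over operons and bars are quartiles over operons, 1 library per strain and time. At 9 min the medians run from 9.41% in JS38 to 31.1% in JS299.

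Fitted operon half-lives were shortest in JS38 and longest in JS299. The median was 2.65 min in JS38 (95% interval over operons 2.43 to 2.89, 467 operons), 2.97 min in JS221 (2.87 to 3.06, 1001 operons), 3.31 min in JS233 (3.24 to 3.38, 1123 operons) and 3.93 min in JS299 (3.85 to 4.02, 1363 operons). These sets differ in size because more JS38 operons were blank at 9 min. Over the 441 operons with a half-life in all 4 strains, the medians were 2.50, 3.57, 3.86 and 5.00 min. In that shared set the lower and upper quartiles were 1.90 and 4.42 min in JS38, 2.62 and 6.25 min in JS221, 3.08 and 5.10 min in JS233, and 3.82 and 8.51 min in JS299. Straight lines described the courses with a median R2 of 0.972, 0.971, 0.950 and 0.948. Without the 9 min samples the medians were 1.67, 1.93, 2.13 and 2.41 min, over other sets of 1031, 1654, 1526 and 1705 operons. These sets add operons that are blank at 9 min, so the shorter medians do not show a faster early decay.

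**Figure D2:**
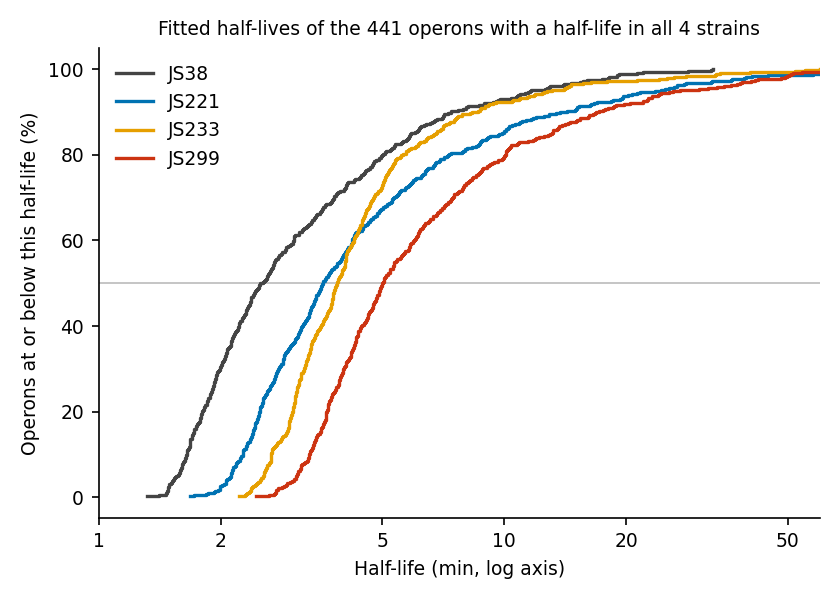
Cumulative percentage of operons (y axis) at or below a fitted half-life (min, log x axis) for the 441 operons with a half-life in all 4 strains, 1 line per strain; the grey line marks 50%. The medians are 2.50 min in JS38, 3.57 min in JS221, 3.86 min in JS233 and 5.00 min in JS299.

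Operons decayed more slowly in JS221 than in JS38. The median log2 half-life ratio was 0.49 over 454 operons (95% interval over operons 0.46 to 0.53), a factor of 1.41, and 409 of these operons had the longer half-life in JS221. By the rule of size, 58 operons were at least 2-fold longer-lived and 1 was at least 2-fold shorter-lived, or 22 and 6 after division of the ratios by their median. Of the 6 largest rises under the fixed rule, between 3.05-fold and 4.52-fold, 5 passed the limma slope test, while the 6 largest falls, between 1.35-fold and 1.54-fold, had adjusted p of 0.0697 to 0.641. In the limma slope test, 133 of 462 operons had a slower decay at adjusted p below 0.05 and 0 had a faster one, with 202 slower and 3 faster at an unadjusted p below 0.05. Without the 9 min libraries, where more operons were tested on fewer samples, limma called 8 of 1057 operons slower and 0 faster, with 204 and 1 at an unadjusted p below 0.05, while 98 of 1023 operons were at least 2-fold longer-lived and 31 shorter-lived, and 5 were shorter-lived without the 0 min libraries. Fitted on these strains alone, 39 operons were called slower.

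Operons of JS233 had longer half-lives than those of JS38 in 371 of 457 cases, and both directions held operons past the test. The median log2 half-life ratio was 0.58 (95% interval over operons 0.50 to 0.63), a factor of 1.49. Of these operons 72 were at least 2-fold longer-lived and 13 at least 2-fold shorter-lived, or 20 and 38 after division of the ratios by their median. Of the 6 largest rises under the fixed rule, between 3.50-fold and 7.43-fold, 6 passed the limma slope test, and of the 6 largest falls, between 2.06-fold and 3.79-fold, 3 passed. The limma slope test called 169 of 462 operons slower and 9 faster at adjusted p below 0.05. Without the 9 min libraries limma called 6 of 1057 operons slower and 0 faster, with 392 and 13 at an unadjusted p below 0.05, and 306 of 977 operons were at least 2-fold longer-lived. Fitted on these strains alone, limma called 90 operons slower and 0 faster, with 171 and 7 at an unadjusted p below 0.05. Among the non-coding RNAs, CCNA_R0134 had a half-life of 5.87 ± 0.25 min (SE of the fit) in JS38 and 22.9 ± 13.3 min in JS233, and its slope difference was called slower (limma adjusted p = 0.00333, and 0.0664 without the 9 min libraries, the highest of 7 alternatives whose lowest was 0.000714). That slope difference was 0.13 log2 per min (SE 0.025), and 0.21 (SE 0.058) without the 9 min libraries.

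JS299 showed the longest half-lives relative to JS38. The median log2 ratio was 1.00 over 453 operons (95% interval over operons 0.94 to 1.06), and 432 of them had the longer half-life in JS299. At least 2-fold longer half-lives were fitted for 228 operons and at least 2-fold shorter ones for 1, or 33 and 21 after division of the ratios by their median. The limma slope test called 271 of 462 operons slower and 0 faster at adjusted p below 0.05, with 305 slower and 0 faster at an unadjusted p below 0.05. With the 9 min libraries left out, 299 of 1057 operons were called slower, and 523 of 965 were at least 2-fold longer-lived and 7 shorter-lived. Of the 6 largest rises under the fixed rule, between 5.35-fold and 7.02-fold, 5 passed the test. The first among them were operon 174, from 1.48 ± 0.17 min in JS38 to 10.4 ± 1.4 min in JS299 (limma adjusted p = 0.000269), and operon 1499, from 3.82 ± 0.50 to 26.1 ± 14.0 min (limma adjusted p = 0.000215, and 0.0977 without the 9 min libraries, the highest of 7 alternatives whose lowest was 1.09e-05). The slope difference of operon 1499 was 0.22 log2 per min (SE 0.031), and 0.19 (SE 0.080) without the 9 min libraries. At the other end, operon 1641.1 had 12.5 ± 3.5 min in JS38 and 7.26 ± 0.66 min in JS299 (limma adjusted p = 0.146), and operon 1006 had 6.43 ± 1.00 and 4.19 ± 0.52 min (limma adjusted p = 0.129). Neither passed the test, except operon 1006 with a time curve shared by the strains (adjusted p = 0.0232, the lowest of 7 alternatives whose highest was 0.249). Scaled to tRNA, the median log2 ratio was 0.67 and 104 operons were at least 2-fold longer-lived.

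Among the other strains, JS299 operons decayed more slowly than those of JS221, with a median log2 half-life ratio of 0.50 over 969 operons (95% interval over operons 0.46 to 0.53). The ratio of JS233 over JS221 was 0.26 over 909 operons (0.23 to 0.29) and that of JS299 over JS233 was 0.21 over 1063 operons (0.19 to 0.24). Over the 441 operons with a half-life in all 4 strains these ratios were 0.093 for JS233 over JS221 and 0.41 for JS299 over JS233. The limma slope test at adjusted p below 0.05 called 40 operons slower and 0 faster in JS299 than in JS221, 104 slower and 3 faster in JS299 than in JS233, and 21 slower and 31 faster in JS233 than in JS221, the last 19 and 17 with levels scaled to tRNA. At an unadjusted p below 0.05, 133 operons were slower and 1 was faster in JS299 than in JS221. With levels scaled to tRNA the median log2 ratio was 0.031 for JS299 over JS233 and 0.29 for JS299 over JS221, and limma called 0 operons slower and 0 faster in JS299 than in JS221, with 80 and 2 at an unadjusted p below 0.05, and 30 slower and 3 faster in JS299 than in JS233. When the 9 min libraries were left out, limma called 17 operons slower and 1 faster in JS299 than in JS233 and 0 in either direction in the other pairs, with 94 slower and 0 faster at an unadjusted p below 0.05 in JS299 than in JS221 and 82 slower and 39 faster in JS233 than in JS221.

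Operons kept much of their rank order of half-life between strains. Across operons, Spearman's rho of half-lives against JS38 was 0.89 for JS221 (454 operons), 0.77 for JS233 (457) and 0.71 for JS299 (453). It was 0.75 between JS221 and JS233, 0.79 between JS221 and JS299 and 0.59 between JS233 and JS299. These 6 correlations are across operons, which are not independent replicates, so no p is given.

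Among features with a value in every library, non-coding RNAs were far more stable than operons in all 4 strains. These were 58 of the 118 non-coding RNAs with any value, and the choice favours stable ones. Their median level at 9 min was 99.0% of the 0 min level in JS38, 103% in JS221, 92.2% in JS233 and 109% in JS299. Relative to tRNA, which rose as a share of the reads, these medians were 70.2%, 71.6%, 71.0% and 67.8%. The number below 50% of the 0 min level at 9 min was 12 in JS38, 4 in JS221, 3 in JS233 and 7 in JS299. In the limma slope test, 3 of the 58 were slower in JS221 than in JS38, 7 in JS233 and 5 in JS299 at adjusted p below 0.05, and 0 were faster in these comparisons, with 0, 3 and 0 faster at an unadjusted p below 0.05. Adjusted over the list alone, 1 was slower in JS221, 7 in JS233 and 2 in JS299, and 0 were faster.

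CCNA_R0019 and CCNA_R0097 were called slower than in JS38 in all 3 comparisons, which share the JS38 libraries. The half-life of CCNA_R0019 was 5.24 ± 0.28 min (SE of the fit) in JS38, 13.1 ± 1.4 min in JS221, 12.6 ± 3.2 min in JS233 and 23.9 ± 2.9 min in JS299, with limma adjusted p of 0.00955, 0.00567 and 0.000517. The other calls were CCNA_R0134 in JS221 and JS233, CCNA_R0115 in JS233 and JS299, CCNA_R0108, CCNA_R0187 and CCNA_R0196 in JS233, and CCNA_R0040 and CCNA_R0199 in JS299. Fitted on the 2 strains alone and adjusted over the list alone, limma called 0 non-coding RNAs slower in JS221, JS233 and JS299. At an unadjusted p below 0.05 there were 5, 7 and 7 slower. Adjusted over all features, it called 0 slower in JS221, 6 in JS233 without CCNA_R0019, and 3 in JS299. The adjusted p of CCNA_R0019 was then 0.0544 in JS221 (range over 7 alternatives 0.00239 to 0.418) and 0.0626 in JS233 (0.00212 to 0.122), and that of CCNA_R0097 was 0.0874 in JS221 (0.00346 to 0.896). The slope differences of CCNA_R0097 in JS221, JS233 and JS299 were 0.12, 0.15 and 0.20 log2 per min, and 0.037, 0.082 and 0.060 without the 9 min libraries, where its adjusted p was 0.608 in JS233 (range over 7 alternatives 0.000495 to 0.608) and 0.679 in JS299 (5.03e-05 to 0.679). Those of CCNA_R0019 were 0.11, 0.11 and 0.15, and 0.12, 0.20 and 0.17 without these libraries. Scaled to tRNA, CCNA_R0019 and CCNA_R0097 were the 2 non-coding RNAs called slower in JS299. Without the 9 min libraries limma called 0 of 70 non-coding RNAs slower in JS221 and JS233, with 2 and 6 slower at an unadjusted p below 0.05, and 2 in JS299, CCNA_R0117 and crfA, named after their values were seen. The half-lives of CCNA_R0134 and CCNA_R0196 were 5.87 ± 0.25 and 6.10 ± 0.79 min in JS38, 12.2 ± 2.2 and 9.67 ± 0.89 min in JS221 and 6.57 ± 0.71 and 6.66 ± 0.66 min in JS299. Against JS38, CCNA_R0134 did not pass the test in JS299 (limma adjusted p = 0.587) and CCNA_R0196 did not pass in JS221 or JS299 (0.129 and 0.711), except in JS221 with a time curve shared by the strains (0.0443, the lowest of 7 alternatives whose highest was 0.634). crfA, a small RNA induced by carbon starvation whose annotation overlaps CCNA_R0079, had half-lives of 3.53 ± 1.24 min in JS38, 5.57 ± 1.54 min in JS221, 5.73 ± 1.38 min in JS233 and 5.97 ± 0.74 min in JS299, which did not pass the test against JS38 (limma adjusted p 0.332, 0.268 and 0.22), except JS299 without the 9 min libraries (0.0497, the lowest of 7 alternatives whose highest was 0.44).

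Among non-coding RNAs with a half-life in both strains, the median gain in JS299 lay below that of features of like abundance. The median log2 half-life ratio of JS299 over JS38 was 0.37 over 24 members with a half-life in both strains, 18 of them above 0, while level-matched random lists had a typical median of 1.19 and 0 of 10000 fell below the list. A half-life needs a falling slope, so RNAs with no negative slope in JS299, such as CCNA_R0002, CCNA_R0118 and CCNA_R0121, are left out of this median, which therefore depends on the outcome itself. CCNA_R0096, at the low end under the fixed rule, had 19.1 ± 5.5 min in JS38 and 10.8 ± 0.5 min in JS299 (limma adjusted p = 0.393). In JS221 the list median was 0.66 over 21 members, at percentile 70.7 of the random lists, and in JS233 it was 0.63 over 29 members, at percentile 91.8. Scaled to tRNA, where few members are left out, the JS299 list median was -0.064 over 56 members and the percentiles were 15.7 in JS221, 2.32 in JS233 and 0 in JS299. The extreme members were CCNA_R0002 (log2 ratio 4.49) and CCNA_R0186 (-1.31) in JS221, CCNA_R0196 (2.93) and CCNA_R0088 (-4.66) in JS233, and CCNA_R0115 (7.93) and CCNA_R0144 (-0.91) in JS299. For each of these 6 RNAs the SE of the fit exceeded the half-life in at least 1 of the strains compared, as for CCNA_R0186 in JS38 (122 ± 391 min) and CCNA_R0196 in JS233 (46.4 ± 49.6 min). Of the tRNAs, 35 of 36 ended above their 0 min level in JS38, JS221 and JS299 and 30 in JS233, and 1 had a half-life in both strains of each pair. The limma slope test called 0 tRNAs in JS221 against JS38 (0 at an unadjusted p below 0.05), 5 faster in JS233 and 2 slower in JS299. Adjusted over the list alone, 1 was faster in JS233 and 0 slower in JS299 (limma, 4 slower at an unadjusted p below 0.05). Without the 9 min libraries limma called 0 tRNAs in JS233 (4 faster and 2 slower at an unadjusted p below 0.05) and 0 in JS299. Fitted on the 2 strains alone, 1 was faster in JS233 and 3 were slower in JS299. Scaled to tRNA, 3 were faster and 1 slower in JS233, and 1 was slower in JS299. That scaling divides by the sum of these same 36 tRNAs, so calls in both directions among them can be built in.

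Before rifampicin, operon levels differed most from JS38 in JS299. The median log2 ratio at 0 min was 0.51 over 2015 operons (95% interval over operons 0.49 to 0.54), with 288 operons at least 2-fold higher and 15 at least 2-fold lower. JS221 had a median of 0.20 over 2014 operons, with 33 higher and 7 lower. JS233 had a median of -0.027 over 2007 operons, with 24 higher and 22 lower. Across operons the levels ranked alike, with Spearman's rho against JS38 of 0.97 in JS221, 0.97 in JS233 and 0.95 in JS299. The direction of these counts depends on the scaling. With the median ratio set to 0, JS299 had 52 operons higher and 54 lower and JS221 had 13 higher and 15 lower, while scaled to tRNA the medians were 0.33 in JS221, -0.10 in JS233 and 1.00 in JS299. The counts were then 62 higher and 4 lower in JS221, 18 and 33 in JS233, and 1011 and 8 in JS299.

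Several non-coding RNAs differed between strains at 0 min by more than counting error, and the following were chosen after their values were seen. chvR is a small RNA under the control of the response regulator ChvI and represses the outer-membrane receptor gene chvT. Its level at 0 min was 2716 RPKM in JS38, 3603 in JS221, 498 in JS233 and 15429 in JS299. That is 5.68-fold higher in JS299 than in JS38 (95% counting interval 5.45 to 5.92, 20466 and 2616 reads) and 5.45-fold lower in JS233 (4.98 to 5.97, 573 reads). At the 4 time points the JS299 fold ranged from 5.68 to 8.92 and the JS233 fold from 3.66 to 7.37, in libraries from the same cultures.

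CCNA_R0199, CCNA_R0088 and CCNA_R0092 followed the same order of strains as chvR. CCNA_R0199 was 8.89-fold higher than in JS38 in JS299 (95% counting interval 8.60 to 9.19), 3.96-fold higher in JS221 (3.82 to 4.10) and 3.17-fold lower in JS233 (2.98 to 3.36). CCNA_R0088 was 6.10-fold higher in JS299, 2.76-fold higher in JS221 and 4.08-fold lower in JS233. CCNA_R0092 was 4.55-fold higher, 3.00-fold higher and 5.22-fold lower in the same comparisons. CCNA_R0158 was 10.9-fold higher than in JS38 in JS233 (10.3 to 11.7), 1.55-fold higher in JS221 (1.44 to 1.68) and 6.17-fold lower in JS299 (5.34 to 7.13). Each of these directions was also seen with levels scaled to tRNA and with the median ratio of operons set to 0.

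gsrN, a small RNA of the general stress response, stood at 29512 RPKM in JS38, 57149 in JS221, 30359 in JS233 and 55327 in JS299. crfA was 2.58-fold higher in JS299 than in JS38 (95% counting interval 2.44 to 2.73) and 1.05-fold lower in JS233 (0.98 to 1.12). CCNA_R0155 was 18.0-fold higher in JS299 (14.2 to 22.8) from 71 reads in JS38 and 1761 in JS299. Over all non-coding RNAs with a value in both strains, 18 of 106 were at least 2-fold higher and 6 at least 2-fold lower in JS299 than in JS38, against 35 and 4 scaled to tRNA and 8 and 18 with the median ratio of operons set to 0. In JS233 15 of 106 were higher and 6 lower, and in JS221 10 of 107 were higher and 0 lower.

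**Figure D3:**
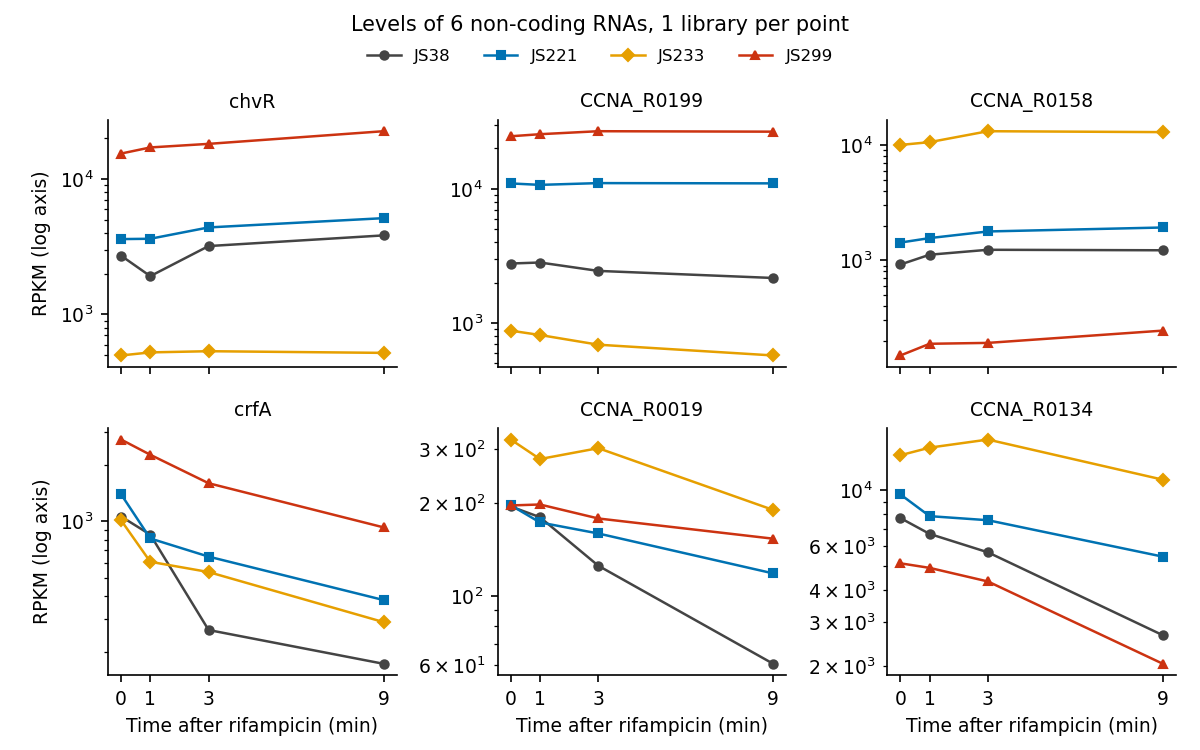
RPKM (log axis) of chvR, CCNA_R0199, CCNA_R0158, crfA, CCNA_R0019 and CCNA_R0134 against time after rifampicin (min); each point is 1 library and each line 1 strain. chvR is highest in JS299 (15429 RPKM at 0 min) and lowest in JS233 (498 RPKM), and CCNA_R0158 is highest in JS233 (10046 RPKM) and lowest in JS299 (149 RPKM).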

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

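The tests of scaling and of blanks and all chvR tests in this part were chosen only after the result was seen, while those of a late drug action and of exchanged strain names were chosen before. The test of a late drug action used the operons chosen by 0 min level, a set that was itself chosen after seeing the data. The effect of time after rifampicin differed between strains by the test of the slope difference itself for some features of each pair. The number of features with a different slope at adjusted p below 0.05 in limma was 136 for JS221 and JS38, 190 for JS233 and JS38, 278 for JS299 and JS38, 55 for JS233 and JS221, 40 for JS299 and JS221 and 115 for JS299 and JS233, of 556 tested. For JS299 and JS221 limma called 0 scaled to tRNA (88 at an unadjusted p below 0.05) and 0 without the 9 min libraries (94), and for JS233 and JS221 0 without the 9 min libraries (131). Exchanging the names of both strains within time points gives 8 arrangements per pair, too few for a share under 0.05. For JS221 and JS38, 4 of the 8 gave at least the real 136 calls, and the highest other gave 253. For JS233 and JS38, 3 of the 8 gave at least the real 190, and the highest other gave 250. For JS299 and JS38, 4 of the 8 gave at least the real 278, and the highest other gave 456. The highest other arrangement was in each case the exchange of the 9 min libraries alone. That exchange joins the earlier libraries of each strain to the 9 min library of the other strain. A real difference between the strains in level or at 9 min then yields calls by itself. The counts under exchange are therefore no measure of chance, and no conclusion on the real calls was drawn from them.

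The pattern of longer operon half-lives than in JS38 was weighed in JS299, where it was largest. Division of all levels by the tRNA sum lowered the median log2 half-life ratio from 1.00 to 0.67 (95% interval over operons 0.61 to 0.73), so scaling to libraries dominated by tRNA may account for part of the difference and not for all of it. Loss of unstable operons to blanks is argued against as the whole cause, because among operons chosen by 0 min level the median share left at 9 min was 4.79 times as high in JS299 as in JS38. A late start of the rifampicin block in 1 culture would leave the rate from 3 to 9 min alike, but the JS38 rate exceeded the JS299 rate there by a median log2 ratio of 0.84 (0.77 to 0.93). The same ratio was 0.54 (0.48 to 0.59) against JS233 and 0.36 (0.30 to 0.41) against JS221. The value for JS221 lay between the limits written for JS299, so a late start is undecided for JS221. A difference between strains and a difference between single cultures, such as incomplete drug action in 1 of them, both stay open, since each strain was grown once.

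The level of chvR in JS233 and JS299 was weighed next. An error in 1 library is argued against by the lowest JS299 library, whose level was 4.02 times that of the highest JS38 library, while the highest JS233 library (535.5 RPKM) lay below the lowest JS38 library (1919 RPKM). In JS299 the values showed no clearly slower decay. The share of chvR left at 9 min relative to tRNA was 0.91 times that in JS38, while the unscaled shares were 146.2% in JS299 and 141.3% in JS38. The slope difference was -0.024 log2 per min (SE 0.033) unscaled and -0.045 (SE 0.031) scaled to tRNA, both on the side of a faster decay. chvR in JS38 lost almost nothing in 9 min (100.1% left relative to tRNA), so there was little decay for JS299 to slow. Losses too slow to show within 9 min cannot be judged, so decay and synthesis are not fully told apart. In JS233, where the level was lower, 80.4% was left, 0.80 times the share in JS38, and a faster decay there stays open, since the slope difference did not pass the test (limma adjusted p = 0.0957, range over 7 alternatives 0.0572 to 0.614). A strain difference in synthesis remains an untested hypothesis.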

How the results depend on the processing

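Scaling to tRNA, a time curve shared by the strains, fits with at least 3 values per strain and operons chosen by 0 min level were chosen after seeing the data. Of 833 recomputed values of single named RNAs and operons, 671 stayed on the same side of the test or within their error, 122 moved, 32 lost and 6 gained a call, and 2 reversed. The reversals were CCNA_R0092 in JS233 over JS38 without the 1 min libraries (log2 half-life ratio -0.21) and CCNA_R0096 without the 0 min libraries (-0.27). The median log2 half-life ratios against JS38 stayed above 0 under each alternative run except division by the median, which sets them to 0. They lay between 0.42 and 0.55 for JS221, 0.55 and 0.74 for JS233 and 0.67 and 1.06 for JS299. Except where an alternative itself changes the set of operons or the size rule, the cause was not tested.

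Operons at least 2-fold longer-lived and shorter-lived than in JS38 numbered, after division by the median ratio, 22 and 6 in JS221, 20 and 38 in JS233 and 33 and 21 in JS299. With a 1.5-fold rule they were 177 and 4, 222 and 27, and 350 and 3, and with a 3-fold rule 19 and 0, 20 and 6, and 65 and 0. With half-lives of 0.2 to 27 min the shorter-lived were 0, 7 and 0, and with R2 of at least 0.8 they were 0, 5 and 0. Including non-coding RNAs and tRNAs, JS221 had 2, and among operons above the median 0 min level 0, where the median ratio of JS299 over JS233 was 0.27. Pearson's r of log2 half-lives of JS299 and JS38 was 0.77.

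Among operons with a half-life in all 4 strains, the medians were 3.57 min in JS221, 3.86 in JS233 and 5.00 in JS299, with 0 shorter-lived operons in JS221 and 7 in JS233. The ratios were 0.093 for JS233 over JS221 and 0.41 for JS299 over JS233. Without the 9 min libraries, over larger sets that add operons blank at 9 min, the medians were 1.67, 1.93, 2.13 and 2.41 min. The ratios were then 0.43 for JS221 and 0.74 for JS233. The longer-lived operons were 98, 306 and 523, with 31 shorter-lived in JS221 and 7 in JS299. Without the 1 min libraries the medians were 3.39 min in JS233 and 4.06 in JS299, JS221 and JS299 had 2 shorter-lived operons each, and JS299 over JS221 was 0.53. Without the 0 min libraries the medians were 3.12, 3.48 and 4.09 min in JS221, JS233 and JS299, the ratio of JS221 was 0.55, JS221 and JS299 had 5 shorter-lived operons each, JS299 over JS221 was 0.43 and JS299 over JS233 0.18.

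Scaled to tRNA, the medians were 2.33, 2.58, 2.93 and 3.05 min. The ratio of JS221 was 0.42, with 29 longer-lived and 3 shorter-lived operons. JS233 had 4 shorter-lived, and JS299 had a ratio of 0.67 with 104 longer-lived and 4 shorter-lived. JS299 over JS221 was 0.29 and JS299 over JS233 0.031. The median share left at 9 min was 6.67%, 12.7%, 16.4% and 19.4% scaled to tRNA, and 4.26%, 8.37%, 13.4% and 20.4% among operons chosen by 0 min level. The percentile of the non-coding list in JS221 and JS233 was 15.7 and 2.32 scaled to tRNA, 96.5 and 68.9 among unmatched random lists, and 84.6 and 100 with half-lives of 0.2 to 27 min.

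At 0 min, operons at least 2-fold higher and lower numbered 13 and 15 in JS221 and 52 and 54 in JS299 with median-ratio scaling, and 62 and 4, and 1011 and 8, scaled to tRNA. With a 3-fold rule they were 3 and 2 in JS221, 10 and 2 in JS233 and 37 and 8 in JS299. In the limma slope test without the 9 min libraries, 8 operons were slower in JS221 and 6 in JS233, where 0 were faster (13 at an unadjusted p below 0.05). Scaled to tRNA, 2 were faster in JS233. With the shared curve, 261 were slower and 6 faster in JS221, 258 and 17 in JS233, and 3 faster in JS299. With at least 3 values per strain 334, 509 and 683 of 1063 operons were slower, while the main test covered 462 operons. The larger set admits operons with a blank, and blanks were most frequent in JS38 at 9 min. For an operon blank there, the JS38 line covers a shorter time span than a line that reaches 9 min. These counts are therefore not directly comparable with those of the main test. With the 2 strains alone 39 were slower in JS221 and 90 in JS233, where 0 were faster (7 at an unadjusted p below 0.05).

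Blanks, taken as 50 reads or fewer, limit half-lives most in JS38, where 1870 features were blank at 9 min. In JS38 472 operons were fitted, 1063 without the 9 min library and 476 without the shallow 1 min library of 4841645 reads. With 1 library per strain and time point, leaving out a replicate was not possible. Alternatives for deposited half-lives and raw counts were not run because the table holds RPKM, and that for runs of neighbouring list members was not run because operons carry no gene names.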

Other observations

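The test of blanks at 9 min, those of run-off and of blanks against JS221 and the comparison of level ratios were chosen only after the results were seen, while the other tests here were chosen before them. The test of blanks by the share left at 3 min against JS38 used operons chosen by 0 min level, a set chosen after seeing the data. Non-coding RNAs that were higher in JS299 than in JS221 tended to be lower in JS233 than in JS38. Over 105 non-coding RNAs, Spearman's rho between the 0 min log2 ratio of JS299 over JS221 and that of JS233 over JS38, which share no library, was -0.48 (95% bootstrap interval over RNAs -0.64 to -0.30). Over 2003 operons it was -0.20 (-0.25 to -0.16). CCNA_R0044 and CCNA_R0181 were 4.72-fold and 5.14-fold higher in JS233 than in JS38. In JS299 their log2 ratios were 0.41 and -0.038. Scaled to tRNA these were 0.90 and 0.45, and with the median ratio of operons set to 0 they were -0.10 and -0.55. The JS299 change of both RNAs therefore depends on the scaling. CCNA_R0097 was 4.68-fold higher in JS233 and 3.24-fold lower in JS299 at 0 min, with folds over the 4 time points of 4.68 to 11.8 and of 1.01 to 3.24. These RNAs were chosen after their values were seen.

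Longer operons gained more half-life relative to JS38 in JS233. Across 457 operons, Spearman's rho of recovered length with the log2 half-life ratio of JS233 over JS38 was 0.49 (95% bootstrap interval over operons 0.41 to 0.57), against -0.015 (-0.11 to 0.076) for JS221 and 0.16 (0.065 to 0.25) for JS299. Given the 0 min level, the partial rho was 0.47 for JS233, 0.11 for JS221 and 0.31 for JS299, a narrower contrast. Directly compared, JS299 over JS233 had a rho of -0.12 (-0.18 to -0.056) with a partial rho of -0.00024 given the 0 min level, and from 0 to 3 min a rho of -0.050 (-0.10 to 0.0078). The median ratio of JS233 was 0.20 among the 72 operons of up to 719 nt and 0.77 among the 218 operons of at least 2246 nt. In JS38 itself, longer operons had shorter half-lives (rho -0.44 over 467 operons), and in JS233 rho was 0.038 over 1123 operons. Without the 9 min libraries these values were 0.049 over 1031 operons in JS38 and 0.32 over 1525 in JS233, and 0.32 over 1704 in JS299. The rho of length with the log2 ratio was then 0.44 (0.39 to 0.50) for JS233 over JS38 and 0.28 (0.22 to 0.34) for JS299 over JS38, and with JS221 as the reference 0.33 (0.28 to 0.38) for JS233 and 0.38 (0.34 to 0.43) for JS299. Among operons chosen by 0 min level, JS299 over JS38 gave 0.11 (-0.0065 to 0.21) for half-lives from 0 to 9 min and -0.096 (-0.18 to -0.0080) for the share left at 3 min, so its direction depends on the measure. In that set JS299 over JS233 gave -0.23 (-0.31 to -0.14) from 0 to 9 min, -0.29 (-0.36 to -0.20) from 0 to 3 min and -0.40 (-0.47 to -0.33) for the share left, with partial rho of 0.016, 0.037 and -0.21, and JS221 over JS38 gave -0.21 (-0.30 to -0.12) for half-lives from 0 to 3 min.

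For this length trend, rho was still 0.38 (0.29 to 0.46) for rates from 3 to 9 min against JS38 and 0.13 (0.064 to 0.20) against JS221. That test of run-off assumes that polymerases have left most operons by 3 min. Lengths reached 19374 nt and elongation rates were not measured, so run-off may last longer on the longest operons. Run-off therefore stays open against both references. An oddity of the JS38 libraries is argued against as the whole cause by a rho of 0.35 (0.29 to 0.41) from 0 to 9 min with JS221 in their place. Blanks at 9 min are argued against by a rho of 0.49 (0.41 to 0.56) for half-lives from 0 to 3 min among operons chosen by 0 min level (partial rho 0.26 given the 0 min level). The share left at 3 min in that set gave 0.20 (0.12 to 0.28, partial rho -0.12) against JS38, which leaves blanks for features of 50 reads or fewer open there, and 0.44 (0.37 to 0.51, partial rho 0.18) against JS221, which argues against them as the whole cause there. A strain difference that acts on long transcripts may underlie the trend, as a hypothesis found and tested on the same single cultures.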
